A study of Mus musculus with 12 samples.

How the data were processed

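The series holds 12 arrays of mouse eyelid RNA, each a 2-colour hybridisation on an Agilent mouse array with 60-base probes. Eyelids of wild-type and Tabby embryos were sampled at embryonic days 14.5, 15.5 and 16.5, with 2 arrays in each of the 6 groups, which the labels call biological replicates. The eyelid RNA carried the green dye Cy3 and a common reference carried the red dye Cy5 on every array, per the labels, so no dyes were swapped. Per the labels' protocols, the reference was a pool of RNA from mouse cell lines mixed with embryonic stem cell RNA, and RNA was extracted with TRIzol and amplified and labelled with an Agilent linear amplification kit. The treatment protocol in the labels speaks of footpad skin at other ages, whereas the title, source and tissue of every sample give eyelids; the groups follow the sample labels.

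The deposited scanner files give spot intensity in both channels as extracted by Agilent Feature Extraction 9.5.1.1, per the file headers. They also hold Feature Extraction's background-subtracted and dye-normalised processed signals, and its log10 ratio of red over green, per the file headers. The authors also deposited a value table on a log10 scale with 41999 rows. Its scale, centring and direction were not given in the sources used here. Set against the scanner files, each of its columns correlated at r = 1 with log10 of the green processed signal minus the deviation of the log10 red processed signal from that probe's mean over the arrays. Its values therefore rise with eyelid RNA, and its column medians lay between 2.33 and 2.35. That table served as an alternative only.

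Intensities were corrected for background with limma 3.58.1 in R 4.3.3 (normexp on the mean spot signal and median local background, offset 50) and normalised within each array by loess with the 1417 control spots at weight 0. The negative of the resulting log2 ratio gives eyelid over reference, so a positive value means more eyelid than reference signal. Control spots and spots with an outlier flag were left out, and the spots of a repeated probe were averaged (7 probes had 5 spots each). Of 42006 probes, 32981 were tested: those well above background in Cy3 on both arrays of at least 1 group, less 1 probe without a value in a group. The normexp offset draws low ratios towards 0, so fold changes of dim probes are understated.

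A mean for each of the 6 groups was fitted to all 12 arrays with lmFit and contrasts were tested with eBayes, which left 6 residual degrees of freedom. The contrasts were Tabby minus wild type at each stage, the mean of those 3 differences, a moderated F test of whether the difference depends on stage, and wild-type E16.5 minus E14.5. All limma tests were 2-sided with Benjamini-Hochberg adjustment over the probes tested, and a probe was called at an adjusted p under 0.05. The fit was tested on simulated data with 200 changed probes. The data were built from the real probe means and the variances that eBayes estimated, equal in all groups. For the stage-averaged comparison, 94% of probes changed 1.5-fold and 100% of those changed 2-fold were recovered. At E14.5 these shares were 77% and 93%, at E15.5 82% and 94%, and at E16.5 76% and 98%. They were 76% and 99% for the wild-type stage comparison and 30% and 82% for the stage dependence, each with 32981 probes in the fit. Unchanged probes gave 10 calls averaged over stages, 5 at E14.5, 9 at E15.5, 7 at E16.5, 11 between stages and 4 for stage dependence. Changing 200 probes together loosens the cut-off that the adjustment sets. The recovered shares are therefore too high a guide where few probes differ.

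Each slide held the 4 arrays of 1 stage and was scanned on its own. A slide term is therefore absorbed by the group means in genotype comparisons, whereas slide and stage cannot be told apart in stage comparisons. On every slide the wild-type arrays lay at positions 1 and 2 and the Tabby arrays at 3 and 4, so array position and genotype cannot be told apart either.

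The probes carry identifiers without gene symbols, and the gene table used here lists symbols and accessions but none of these identifiers, so 0 probes were named. The plans made before the data were examined that could not be carried out for that reason were choosing 1 probe per gene, testing the gene lists and reporting the level of Eda, the gene mutated in Tabby. Every probe was tested on its own instead. The rule for items to name was to take the highest and lowest log2 differences among called probes whose values did not overlap between genotypes, or stages, in each stage compared, and to fill up by smallest p with probes said not to pass. It was kept with at most 2 probes per direction and comparison, and was limited to probes well above background on all arrays compared; both limits were set after the data were seen. For the stage dependence the probes with the smallest p were taken.

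The alternatives planned before the data were examined were processed signals followed by loess, Feature Extraction's ratio with its sign turned, median centring, quantile normalisation of average intensities, the eyelid channel alone scaled to its 75th percentile, 2 other filters, the authors' value table, only the arrays of the groups compared, stage and replicate number as a block, eBayes with trend and robust options, array weights, a minimum fold of 1.5, and leaving out each array in turn. Averaging without the E15.5 arrays was chosen after seeing the data. A probe not well above background on both arrays of a group has only a bound there. Bounds were taken from the Cy3 channel after loess and quantile normalisation, as the mean of the brighter group against the higher of the dim value and the lowest signal well above background, and are open to dye bias.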

Results

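Gene expression was compared between eyelids of wild-type and Tabby mouse embryos during the days in which the Meibomian glands, the oil glands of the eyelid rim, begin to form. Tabby is a mutation of Eda, which encodes the ligand ectodysplasin that is needed for hair, sweat gland and tooth development, and the series sought genes that depend on it. There were 2 arrays in each of 6 groups (2 genotypes at E14.5, E15.5 and E16.5), and values are log2 ratios of eyelid over common reference RNA. Between 71.1% and 79.2% of the 42006 probes were well above background in the eyelid channel, and no eyelid spot was saturated. The number of arrays limits the precision of every value. As no probe could be tied to a gene here, results are given for probes, with the sequence of those described in full.

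Developmental stage separated the arrays more than genotype did. The first principal component held 76.8% of the variance and ordered the arrays by stage. Replicates of a group correlated at r = 0.977 to 0.994 across probes, arrays of different genotype within a stage at 0.979 to 0.992, and arrays of different stages at 0.852 to 0.971. The lowest replicate correlation was that of wild-type E15.5, whose 2 arrays differed by more than 2-fold at 390 probes, against 22 to 113 probes in the other 5 groups.

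**Figure D1:**
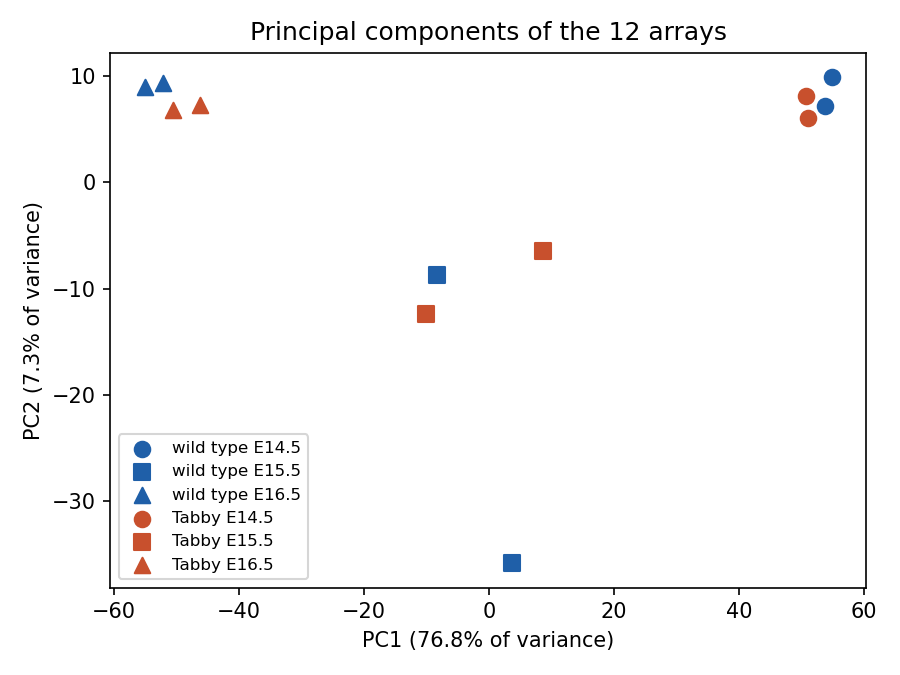
Principal components of the log2 ratios of the 12 arrays, PC1 (76.8% of the variance) against PC2 (7.3%), without units. Each point is 1 array, coloured by genotype and shaped by stage. The stages separate along PC1, and wild-type E15.5 replicate 1 lies apart on PC2 at -35.8.

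The change between E14.5 and E16.5 in wild-type eyelids set the developmental background for the genotype comparisons. Of 32981 probes, 6228 rose and 7117 fell. Among the called probes, 1617 rose and 278 fell at least 2-fold. The risers included probe Z00040994-1, which went from -0.55 ± 0.06 at E14.5 to 7.69 ± 0.36 at E16.5 (SD, n = 2), a log2 change of 8.24 (limma adjusted p = 3.56e-07). Its sequence is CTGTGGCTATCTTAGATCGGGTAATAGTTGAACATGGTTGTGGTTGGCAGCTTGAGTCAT. Probe Z00051631-1 rose by 6.99 (limma adjusted p = 1.65e-06) and had reached 2.23 ± 0.54 at E15.5, between -1.61 ± 0.05 at E14.5 and 5.37 ± 0.09 at E16.5 (SD, n = 2). Among the probes that fell, Z00047077-1 dropped by 5.31 from 8.12 ± 0.13 to 2.80 ± 0.08 (SD, n = 2, limma adjusted p = 2.26e-05). Z00040042-1 dropped by 4.40 from 4.77 ± 0.24 to 0.37 ± 0.16 (SD, n = 2, limma adjusted p = 2.84e-05).

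The stage change was graded in most probes. Of the 1895 called probes that changed at least 2-fold, 1847 (97.5%) had an E15.5 wild-type mean between those of E14.5 and E16.5. Of the 1617 risers, 267 had made under 25% of their rise by E15.5 and 197 had made over 75% of it. Of the 278 probes that fell, 89 had made over 75% of their fall by then. Of all called probes, 277 were not well above background at E14.5 on either array and were at E16.5 on both, 124 of them among the 1617 risers, and 39 of the 277 were at least 10-fold higher at E16.5. In the other direction, 114 called probes were well above background at E14.5 only. The highest lower bound on their fold was 8.08, so none was shown to be 10-fold higher there, though larger falls are possible. Stage and slide cannot be told apart in this comparison. The share of risers among the calls was 46.7%, and it was 35.7% with Feature Extraction's ratio and with the authors' values, 36.9% with the eyelid channel alone and 37.0% with median centring.

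Tabby eyelids went through a similar change. Across all tested probes, which are not independent replicates, the E14.5 to E16.5 change in Tabby correlated with that in wild type at r = 0.965. Both genotypes of a stage shared a slide, so a difference between slides would enter both changes alike and raise their likeness. Of the 1895 wild-type 2-fold probes, 1892 (99.8%) changed the same way in Tabby. The median of their change in Tabby was 90.4% of that in wild type, a share that the choice of probes by the wild-type values can lower.

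**Figure D2:**
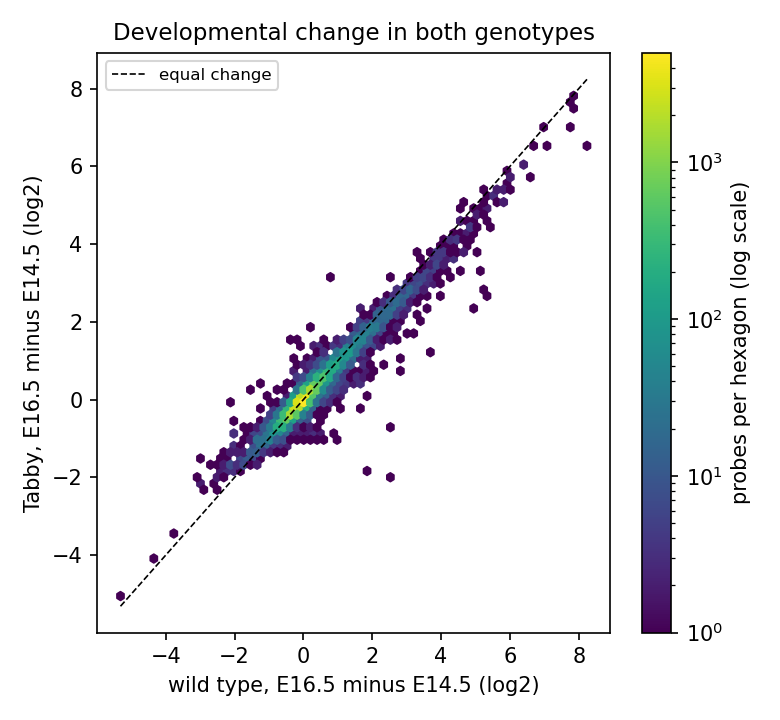
Change from E14.5 to E16.5 in Tabby against the same change in wild type, both on a log2 scale. Hexagons count the 32981 probes on a log colour scale, and the dashed line marks equal change. Most probes lie near the line (r = 0.965 across probes).

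To compare the genotypes over the 3 stages together, the stage differences were averaged. Tabby was lower at 9 probes and higher at 1 (limma, adjusted p under 0.05), while 1932 probes (5.86%) had an unadjusted p under 0.05. Of these 10, 9 differed in the same direction at each stage. The exception was Z00043843-1, which also depended on stage and is described with that comparison. The lowest was Z00036698-1, with the sequence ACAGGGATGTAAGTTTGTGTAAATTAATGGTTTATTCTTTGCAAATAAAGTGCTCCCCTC. It was lower in Tabby by a mean log2 difference of -1.58 (SE 0.149, limma adjusted p = 0.0158), a 2.99-fold difference. Its wild-type means were 1.65 ± 0.12, 1.51 ± 0.25 and 1.67 ± 0.11 at E14.5, E15.5 and E16.5 (SD, n = 2 each). The Tabby means were -0.14 ± 0.09, 0.39 ± 0.68 and -0.15 ± 0.01, and the wide spread at E15.5 came from replicate 2 at 0.87 against -0.10 in replicate 1. Z00074100-1, with the sequence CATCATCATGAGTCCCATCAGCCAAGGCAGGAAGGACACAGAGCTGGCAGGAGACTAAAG, was lower by -0.66 (SE 0.0749, limma adjusted p = 0.0415). The probe higher in Tabby, Z00056287-1, differed by 0.49 (SE 0.0511, limma adjusted p = 0.025). Z00022693-1 was next among the higher probes, at 0.25, and did not pass (limma adjusted p = 0.0767). Of 24 alternatives, the call of Z00074100-1 was lost in 16, that of Z00056287-1 in 14 and that of Z00036698-1 in 6, with limma adjusted p up to 0.553, 0.303 and 0.119. The count of 10 ranged from 6 to 726 when 1 array was left out, the highest without wild-type E15.5 replicate 2, and other groupings of the arrays reached it too, as given in the closing section.

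**Figure D3:**
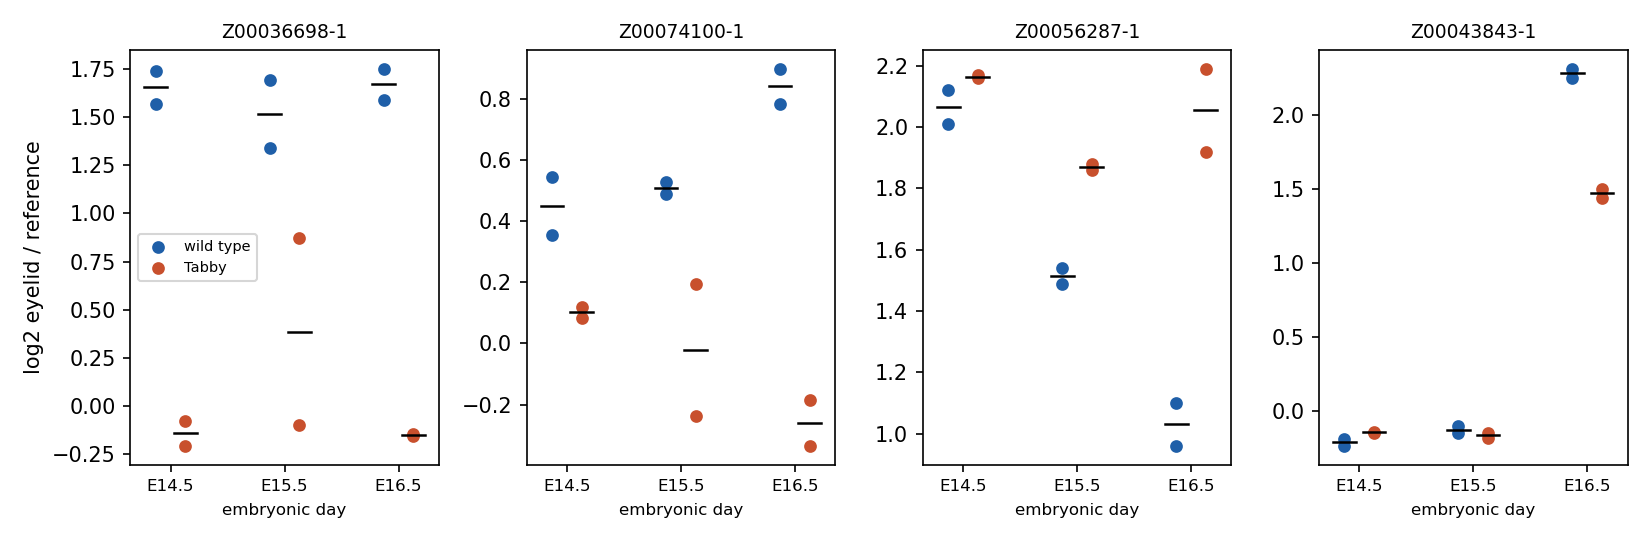
Log2 ratio of eyelid over reference for 4 probes by embryonic day, with 1 point per array, wild type in blue and Tabby in red, and a black bar at the mean of 2 arrays; each panel has its own vertical scale. Z00036698-1 is lower in Tabby at each stage, with E15.5 Tabby replicate 2 at 0.87, and Z00043843-1 has a genotype difference of -0.81 at E16.5.

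At E14.5, when the eyelid was sampled earliest, no probe passed between the genotypes. The limma fit gave 0 calls, and processed signals followed by loess gave 2. An unadjusted limma p under 0.05 was found at 793 probes (2.40%), fewer than that cut-off gives with no difference. The fit pools the spread over all groups. Replicate differences had an SD of 0.279 in wild-type E15.5, against 0.137 and 0.12 in Tabby and wild type at E14.5. The test may therefore be strict at E14.5. With only the E14.5 arrays, 2172 probes had an unadjusted limma p under 0.05 and 0 were called. The smallest p among lower probes was that of Z00074464-1, with a log2 difference of -0.49 (SE 0.0546, limma adjusted p = 0.373), and Z00036698-1 had -1.79 (SE 0.258, limma adjusted p = 0.869). Z00036698-1 passed when either Tabby E15.5 array was left out (limma adjusted p = 0.0242), and Z00074464-1 with array weights (limma adjusted p = 0.043). Among higher probes, Z00058639-1 and Z00025395-1 had differences of 0.57 and 0.56, with limma adjusted p of 0.458 and 0.914; the 2 probes share a run of 50 bases and are not separate measurements.

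At E15.5 no probe passed either, and the count depended on the arrays in the fit. The limma fit gave 0 calls and 2210 probes (6.70%) with an unadjusted p under 0.05. With only the E15.5 arrays these counts were 0 and 1327. There were 2257 calls without wild-type E15.5 replicate 2, 9 without replicate 1, 5 without Tabby E15.5 replicate 2 and 1 without either wild-type E14.5 array. Among lower probes with the smallest p, Z00022648-1 had the most negative difference, at -0.32 ± 0.03 in Tabby against 1.30 ± 0.16 in wild type (SD, n = 2, limma adjusted p = 0.285). Z00076420-1 differed by -0.96, and Z00030279-1 and Z00062260-1 by 0.86 and 0.64, all at a limma adjusted p of 0.285. All 4 passed without wild-type E15.5 replicate 2 (limma adjusted p 0.00557 to 0.00765), and Z00022648-1 also without either wild-type E14.5 array (limma adjusted p = 0.00608). With the eyelid channel alone, the difference of Z00030279-1 turned to -0.13.

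At E16.5, Tabby eyelids were lower at 26 probes and higher at 1. The median log2 difference of the lower probes was -1.04, and 13 of them were at least 2-fold lower. The largest were Z00031819-1, at 0.39 ± 0.59 in Tabby against 2.82 ± 0.58 in wild type (SD, n = 2, limma adjusted p = 0.0332), and Z00042935-1, at 0.71 ± 0.54 against 2.86 ± 0.41 (SD, n = 2, limma adjusted p = 0.0254). The sequence of Z00042935-1 is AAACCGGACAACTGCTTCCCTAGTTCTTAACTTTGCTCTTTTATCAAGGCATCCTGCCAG. Each call was lost in 14 of 24 alternatives, with differences from -3.79 to -2.02 for Z00031819-1 and from -4.17 to -1.27 for Z00042935-1. The higher probe, Z00056287-1 (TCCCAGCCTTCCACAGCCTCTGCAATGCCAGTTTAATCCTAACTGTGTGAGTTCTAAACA), stood at 2.05 ± 0.19 in Tabby and 1.03 ± 0.10 in wild type (SD, n = 2), a difference of 1.02 (SE 0.0886, limma adjusted p = 0.00766), and its call was lost in 6 of 24 alternatives (limma adjusted p up to 0.189). Next among higher probes, Z00050103-1 differed by 0.57 and did not pass (limma adjusted p = 0.0673).

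All 26 lower probes were also called higher at E16.5 than at E14.5 in wild type, with a median rise of 2.38, against 18.9% of all probes. Both comparisons use the same wild-type E16.5 arrays. In 20 simulations of unchanged groups, the median rise of the 26 lower probes of smallest p averaged 0.214, with 0 called higher. Those groups held no stage change, so the simulations gauge only the effect of the shared arrays. They cannot show whether chance differences gather in rising probes that vary more at E16.5. In the mean of both genotypes, 25 of the 26 were called higher, with a median rise of 1.83, against 24.1% of all probes. The error of that mean is independent of the error of the genotype difference only if both genotypes vary alike. Both calls also use the same estimate of a probe's spread, so a low estimate favours both. In Tabby alone 24 were called higher, with a median rise of 1.11. On the mean of both genotypes, 21 of the 26 had made under 25% of the rise by E15.5, as had 8 of the 13 that were well above background on all 8 arrays of E14.5 and E15.5. The median genotype difference of the 26 was -0.02 at E14.5 and -0.07 at E15.5, where the other 13 were not well above background on all arrays, which limits any difference there. Over the 13 measured probes the medians were -0.09, -0.11 and -0.73 at E14.5, E15.5 and E16.5, and 9 of the 13 were lower in Tabby at E14.5 and 13 at E15.5. The 26 probes hold 25 distinct sequences, since Z00070958-1 and Z00071819-1 are identical, and 7 of the 26 were also called in the stage-averaged comparison. At their ends, Z00060172-1 and Z00026043-1 share 36 bases and Z00074464-1 and Z00054827-1 share 8, so the 25 are not all separate measurements. The fit pools the spread over all groups, whereas Z00031819-1 and Z00042935-1 varied more at E16.5 than before. Z00031819-1 had SDs of 0.58 and 0.59 in wild type and Tabby, against 0.0018 to 0.26 earlier, where it was not well above background. For Z00042935-1 they were 0.41 and 0.54, against 0.0076 to 0.18. The SDs of Z00043843-1 stayed at 0.044 or less. A pooled spread can understate the error of probes that vary more at E16.5. All 27 called probes kept their direction under each alternative that tested them, but their calls and sizes did not all hold. There were 0 calls with processed signals, with Feature Extraction's ratio, with the eyelid channel alone and with the authors' values, and the median of the lower probes was -0.79, -0.78, -1.81 and -0.78 under these. With only the 4 arrays of that stage in the fit there were 2 calls, of which 0 were shared, and the count ran from 4 to 71 when 1 array was left out.

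**Figure D4:**
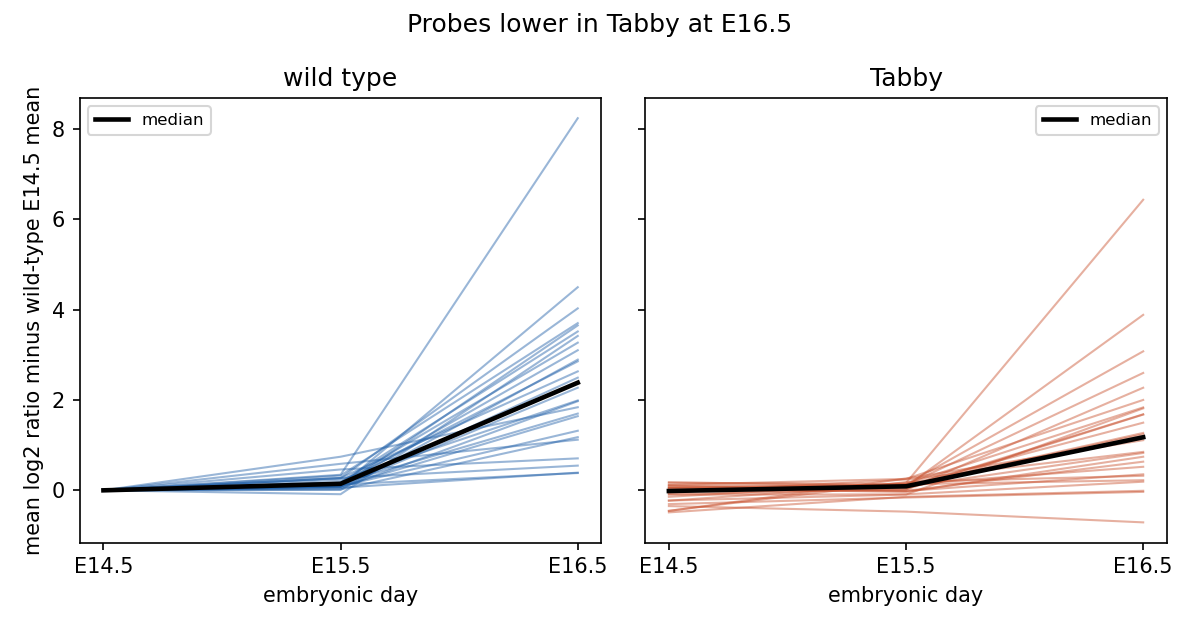
Group mean log2 ratios of the 26 probes lower in Tabby at E16.5, minus the wild-type E14.5 mean of the same probe, by embryonic day. Each coloured line is 1 probe and the black line is the median. The median changes little to E15.5, while single probes differ, and the median rise at E16.5 is larger in wild type (2.38), where the probes were chosen by the genotype difference at that stage.

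The genotype difference depended on stage at 1 probe. Z00043843-1, named because it alone passed, had genotype differences of 0.07, -0.04 and -0.81 at E14.5, E15.5 and E16.5 (limma F test, adjusted p = 0.043). Its sequence is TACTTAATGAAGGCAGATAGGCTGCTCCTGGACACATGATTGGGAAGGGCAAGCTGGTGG. It rose in both genotypes, to 2.28 ± 0.04 in wild type and 1.47 ± 0.04 in Tabby (SD, n = 2). The E14.5 means were -0.21 in wild type and -0.14 in Tabby, and those of E15.5 were -0.13 and -0.16. It was well above background on 1 of the 2 wild-type E15.5 arrays, so a low signal may limit any difference before the rise. Z00076003-1 had the next smallest p and did not pass (limma F test, adjusted p = 0.0601). The call was absent with processed signals, Feature Extraction's ratio, median centring, the eyelid channel alone and the authors' values. It was lost in 9 of the 12 fits that left out 1 array, and 529 probes passed without wild-type E15.5 replicate 2.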

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

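The tests of the reference spot and of stage progress, the slope of the late risers, the interval on the background correction and the counts of the reference channel were chosen after the results were seen; the other tests here were written down before their results were seen.

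Among the 6 Tabby arrays, probe Z00036698-1 was far higher in E15.5 replicate 2 than in the rest, with a gap to the nearest array of 0.881 of the whole range. It was the one such case among 8 sets of 6 arrays. Chance gives about 1 in 20 such sets only if the arrays of a set vary about a common level, whereas each set spans the stages. A defect of the reference spot is argued against, since the eyelid channel alone differed between the Tabby replicates by 1.45 times the difference in the ratio. Replicate 2 lagged along the wild-type stage change, whose squared correlation with the replicate difference was 0.375. That lag predicted -0.00255 of the difference of this probe. The probe changed by 0.01 between E14.5 and E16.5 in wild type, so a lag of any size would predict little of it. Embryo age is therefore argued against only as a shift along that change. Wild-type RNA in the sample remains a candidate explanation: 7 other probes that differed by genotype on the E14.5 and E16.5 arrays lay a median 0.379 of the way from replicate 1 to wild type (95% bootstrap interval 0.11 to 0.791), against 0.601 for Z00036698-1 itself, and 0.498 (0.326 to 0.641) with stage progress removed from each E15.5 array. Their fractions ran from -0.126 to 0.899, and since Eda lies on the X chromosome, an embryo with a wild-type allele among those sampled would act like such a mixture, which was not tested.

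Of the 26 probes lower in Tabby at E16.5, 18 were among the late risers, probes at least 2-fold higher at E16.5 than at E14.5 that had made under 25% of the rise by E15.5, which raises the question of age. A shift of Tabby along the E15.5 to E16.5 change, fitted over all probes, predicted a median 0.121 of their difference (quartiles 0.0754 and 0.225). By the bound set beforehand that share argued against a delay, but the test took early and late risers to shift alike, whereas the fitted slope was -0.102 over all probes and -0.17 in the 180 late risers that were not called; with the latter slope the share was 0.314 for the 18 called late risers (quartiles 0.183 and 0.509), so a delay of late-rising transcripts cannot be told apart from a direct effect of genotype. The reference channel moved the same way as the ratio at the median called probe, which lessens the difference rather than makes it. Its median share in the direction that would produce the difference was -0.233. This argues against hybridisation or array position acting through the reference channel. The background correction stays open as a source of part of the sizes, since the median difference of the called probes under processed signals was 0.819 of the reported one (95% bootstrap interval 0.55 to 1.1), -0.79 against -1.04 for the lower probes, and 0.991 as the median of the ratios per probe, while 23 of the 27 had an unadjusted p under 0.05, the median SE over them rose from 0.0993 to 0.15 and no call was left (smallest adjusted p = 0.0529).

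Wild-type E15.5 replicate 1 stood apart from replicate 2, with an SD of their difference 1.67 times the median of the other 5 pairs. Embryo age is argued against as the whole cause, as the squared correlation of that difference with the Tabby stage change was 0.0461 and the SD ratio stayed at 1.63 with that trend removed, but it may account for part: the correlation of -0.215 has the sign of a younger replicate 1, and the 1617 risers stood at a median 43.5% of their rise in replicate 1 and 60.4% in replicate 2, while the 278 probes that fell stood at 65.0% and 59.7% of their fall. GC content and mean intensity together explained 1.45% of its variance, which argues against a trend with GC content. The intensity part cannot decide, because loess had already removed trends with intensity from each array. Replicate 1 had 71.1% of probes well above background in Cy3, against 78.6% in replicate 2, so a difference in labelling or RNA quality stays open. The reference channel of the pair had 1.26 times the median spread of the other 5 pairs, between the values set for and against an effect of the hybridisation. The Tabby E16.5 pair had a similar reference spread (SD 0.118 against 0.117), while the SD of its ratio difference was 0.175 against 0.279. An effect of the hybridisation cannot be told apart from a difference between the embryos. No biological explanation other than age was tested.

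The genotype difference of Z00043843-1 changed with stage (limma F test, adjusted p = 0.043), as given in the report.

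The reference RNA was the same on all slides, yet 931 probes of its processed signal differed between the wild-type E16.5 and E14.5 arrays, with a median log2 size of 0.812. Of these, 779 were also called in the ratio, against 377 for independent lists, and 739 of the 779 moved the same way as the ratio, which lessens rather than makes a change in the ratio. Of the 931, 655 were higher at E16.5 and 598 differed at least 1.5-fold. After loess and quantile normalisation the reference channel gave 1153 such probes with a median size of 0.336, of which 417 were higher and 330 differed at least 1.5-fold; 791 were shared with the ratio, against 467 for independent lists, and 692 of these moved the same way. Between the genotypes the processed reference signal gave 0 calls at E14.5 and E16.5 and on average and 1 at E15.5, and the normalised one gave 0 in each.

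For the 10 probes called between the genotypes on average over stages, the 4 arrays of each stage were also split in other ways. Of 100 of the 108 such splits, 5 gave as many calls, the real one included, and the highest other split gave 32, so chance is not excluded. The split with 16 calls kept the real genotypes apart at E14.5 and E16.5, so real genotype differences can add to the calls of other splits. The 3 splits with the most calls all set wild-type replicate 1 and Tabby replicate 2 of E15.5 against the other pair of that stage, which points to a structure among those 4 arrays. The same pairs differed in stage progress: the risers stood at 43.5% and 46.1% of the wild-type rise in wild-type replicate 1 and Tabby replicate 2, against 60.4% and 62.6% in wild-type replicate 2 and Tabby replicate 1, and the first principal component was 3.65 and 8.62 against -8.40 and -10.1. The probes that fell did not divide the arrays that way, at 65.0% and 40.4% against 59.7% and 68.6%.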

How the results depend on the processing

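Averaging without the E15.5 arrays was chosen after seeing the data and gave 8 calls against 10. For that stage-averaged comparison the count was 2 with a minimum fold of 1.5, 1 with median centring, 5 with the eyelid channel alone and 17 with trend and robust options. At E14.5, against 0, it was 2 with processed signals, 1 with the authors' values and 1 with array weights. At E16.5, against 27, it was 0 with processed signals, Feature Extraction's ratio, the eyelid channel alone and the authors' values. It was 14 with median centring (11 shared), 54 with trend and robust options (26 shared), and 2 with only the arrays compared (0 shared). In that last fit the spread is estimated from fewer arrays and from that stage alone, where some called probes varied more. The stage dependence, 1 probe, fell to 0 with processed signals, Feature Extraction's ratio, median centring, the eyelid channel alone and the authors' values, and rose to 2 with trend and robust options and 5 with array weights. Between E16.5 and E14.5 in wild type, 4157 of 13345 probes passed a minimum fold of 1.5, and 7584 passed with median centring. Apart from the minimum fold, the cause was not tested. Both other filters kept every count within 1.5 times. Quantile normalisation of average intensities leaves the ratios as they are, so it could move no count. Among the alternatives counted for each named probe it could therefore lose no call. The authors' values nearly repeat Feature Extraction's ratio there, so those 2 are not separate checks. When 1 array was left out, counts ran from 6 to 726 averaged over stages, 0 to 5 at E14.5, 0 to 2257 at E15.5, 4 to 71 at E16.5, 0 to 529 for the stage dependence and 9306 to 14383 for the stage comparison; a group left with 1 array was taken to vary like the others. The same-numbered arrays of a stage deviated with correlations of -0.072, 0.019 and 0.24 at E14.5, E15.5 and E16.5. These values do not establish a pairing by number and cannot exclude one at E16.5. With the replicate block the counts were 3 averaged over stages, 1 of them shared with the 10, and 18 at E16.5, 9 of them shared with the 27. The count for the stage dependence was 0, and the calls at E14.5 and E15.5 stayed at 0. Of the named probes, only Z00030279-1 at E15.5, which did not pass, turned its direction, to -0.13 with the eyelid channel alone. The median difference of all probes was 0.17 at E15.5 with median centring (0.01 as reported), and -0.12 in the stage comparison with Feature Extraction's ratio and the eyelid channel alone (-0.02 as reported). Gene lists, the level of Eda and 1 probe per gene were not run, since the probes are unnamed here. Signal over background limits dim probes, as at most 79.2% of the probes on an array were well above it.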

Other observations

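The tests and values in this part were chosen after the results were seen, except the test of the zinc-finger probes.

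Probes that rose late had a larger median genotype difference than the other risers, a contrast that was not tested. Risers were chosen on the means of both genotypes together, as probes at least 2-fold higher at E16.5 than at E14.5. Of 198 that had made under 25% of the rise by E15.5, 156 (78.8%) were lower in Tabby at E16.5, with a median difference of -0.25. Of the 1346 other risers, which had made 25% or more of the rise by then, 877 (65.2%) were lower, with a median of -0.05. Limited to probes well above background on all 8 arrays of E14.5 and E15.5, 92 of 123 late risers (74.8%) were lower, with a median of -0.22, against 820 of 1256 (65.3%) and -0.04. The late risers held 18 of the 26 called lower probes and the other risers 1. Against the mean of the 4 arrays, the late risers' median level was 0.20 and 0.07 in the wild-type arrays and -0.09 and -0.18 in the Tabby arrays. Under the other scalings the late risers' median ran from -0.18 with median centring to -0.32 with the eyelid channel alone, and that of the other risers turned to 0.03 with median centring. Probes are not independent, so no p is given.

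Some called probes share sequence. Among the 29 probes called at E16.5 or on average, 1 pair was identical over all 60 bases and 3 pairs shared sequence at their ends, over 36, 15 and 8 bases, where random sequence gives about 0.0124 pairs with 8 or more. The pairs sharing 15 and 8 bases join 3 probes that were each lower in Tabby in the stage-averaged comparison. Across the array, 940 tested pairs shared a run of at least 25 bases, and of the 379 pairs with both probes called between E16.5 and E14.5 in wild type, 379 changed the same way.

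Probes whose sequence encodes the linker between C2H2 zinc fingers, a hallmark of a large class of DNA-binding proteins, may have fallen together in wild type. The median change of the 17 tested probes was -0.22, at percentile 1.26 of 10000 random lists matched on mean log intensity, whose central 95% ran from -0.197 to 0.159. Of the 17, 10 fell, 2 rose and the rest did not pass. The class median lay below that of all probes under each scaling, by 0.20 to 0.29. Reading a class from a short probe leaves the genes unnamed, and the slide cannot be told apart from stage here.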
